A study of Mus musculus with 6 samples.

How the data were processed

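COUP-TFII ChIP-seq was done on chromatin from pools of CD-1 mouse mesonephroi at E14.5, with 2 samples from XX and 2 from XY embryos, and with 2 samples of input pooled from both. Grouping by sex and antibody follows the sample titles. The labels' protocol text for extraction names RUNX1 and fetal ovaries, while the titles, tissue, antibody and study design name COUP-TFII and mesonephroi; the latter were used. The submitters' processing notes name the mm10 build and the tools cutadapt, Bowtie 1.2, Picard, HOMER 4.10.3 and bedtools 2.24.0, without their roles. The peak caller's threshold, and how the replicates of a sex were combined, are not given in the sources used here.

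The 2 files used are peak lists that the authors deposited, 1 per sex, each named in the labels of both replicates of that sex. They have 3 columns (chromosome, start and end), and the deposited positions carry no score, height or p-value. All peaks are 300 bp wide. Coordinates are printed counted from 1. Signal tracks and input were not analysed here. The number of reads behind each list is therefore unknown, and a longer list can come from deeper sequencing, better enrichment or more bound sites.

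Gene positions came from a table of NCBI RefSeq genes for GRCm38.p6, the assembly of mm10, with 49943 genes of all kinds, of which 21887 are protein-coding. The match of build was checked: 43.6% of female peaks lay within 500 bp of a gene end, and at most 3.38% did when the peaks were shifted by between 2 and 100 kb. That table gives each gene's start and end but no strand, exons or introns, and no genome sequence was used here. The plan made before the data were examined used transcription start sites, exons and introns, and searched peaks for motifs. Because that information was not used here, each peak was given instead to the nearest protein-coding gene body within 100 kb (distance 0 inside a gene, ties to the nearer gene end), promoters were replaced by 1 kb around either gene end, and motifs were left out. This gave a gene to 93.5% of female and 95.3% of male peaks.

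Peaks were called shared when a female and a male peak had at least 1 bp in common, and shared peaks carry female coordinates. The count was checked against bedtools 2.31.1. A gene can therefore have 1 shared peak more than male peaks where the female and male positions fall nearer to different genes, as at Tex14. Chance overlap came from 1000 random placements of the female peaks on their own chromosomes. Shares have exact (Clopper-Pearson) 95% intervals. The X chromosome against the autosomes, and gene ends against other places, were compared by two-sided Fisher's exact tests with conditional odds ratios. The genome's share in each class was taken at positions every 500 bp between the first and last annotated gene of each chromosome.

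The 23 gene lists were fixed before the data were examined, and all their symbols were found in the gene table. For each list the number of members with at least 1 peak was set against 10000 random lists of as many protein-coding genes, matched on 10 classes of territory length (the stretch of genome nearest to a gene, within 100 kb). The two-sided permutation p cannot go below 0.0002. It was adjusted by Benjamini-Hochberg over the 23 lists, with a threshold of 0.05. These random lists hold genes that are silent in the tissue, since no expression data were used. Female-only and male-only peaks at each list were compared by Fisher's exact test. In 10 simulations of 7483 peaks over 21887 genes, 0 of 230 tests of unchanged lists were called, as were 11 of 50 lists raised 2-fold and 50 of 50 raised 4-fold. Apart from the raised lists, simulated peaks were spread evenly over the genome, without the gathering at gene ends found in the real peaks. Fewer random lists were also drawn per test than for the data. The rates therefore need not hold for the real peaks.

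The genes named by rule are Nr2f2, the 10 genes with most peaks in each list and with most shared peaks, up to 4 members of each gene list with most shared peaks, and members of the androgen and estrogen, Müllerian and Wolffian lists with a peak in 1 sex's list only. The rule also asked for the genes of the 10 highest-scored sex-only peaks of each sex, and because the lists have no score, the 10 genes with most female-only or male-only peaks were taken. Other members are named as examples behind a count, and some genes that the rule or a list takes in are not reported here.

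Alternatives planned before the data were examined were other definitions of a shared peak (50% of each peak, centres within 100 bp, or peaks within 1 kb), gene ends within 2.5 kb, protein-coding genes only, genes within 10 or 500 kb, an exact binomial test on territories, random lists without matching, and unplaced sequences counted with the autosomes. Added afterwards were assignment by the nearest gene end, list membership rotated along the gene order, peaks within or over 1 kb from gene ends, leaving out the X and Y chromosomes, and the 1 kb definition of a shared peak for the chromosome and location tests and for the genes with most sex-only peaks. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with random seed 1.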

Results

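Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of COUP-TFII was carried out on mesonephroi of CD-1 mouse embryos at embryonic stage E14.5. COUP-TFII, encoded by Nr2f2, is an orphan nuclear receptor that is abundant in mesenchyme. The mesonephros is the tissue beside the fetal gonad that holds the Wolffian and Müllerian ducts, the forerunners of the male and female reproductive tracts. The series has 6 samples in 3 groups: 2 of COUP-TFII ChIP from female (XX) mesonephroi, 2 of COUP-TFII ChIP from male (XY) mesonephroi and 2 of pooled input. The data used here are the authors' 2 lists of peaks, 1 per sex, with 11175 peaks in the female list and 9846 in the male list. Every peak is 300 bp wide and has a position (mm10) but no height, score or p-value. Because each sex has 1 list over its 2 replicates, no value below has a spread between replicates, and the depth behind each list is unknown. Tests on peaks therefore compare the 2 lists and not the sexes, and their intervals cover counting error only.

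The first comparison asks how far COUP-TFII occupied the same places in female and male mesonephroi. Peaks at Rbms3, Lrmda, Rad51b, Chd9, Maml3, Chd2, Eif4g2, Itpr1, Phactr2 and Tex14 led the list of genes by number of peaks common to both sexes. Rbms3, an RNA-binding protein gene on chromosome 9 (116572746 to 117629913), had 7 shared peaks among 12 female and 8 male peaks. Lrmda also had 7 shared peaks, and Rad51b, a DNA repair gene, had 6. Some of these genes are long, and a long gene collects peaks by position alone: 3.48 shared peaks would be expected at Rbms3 and 3.19 at Lrmda from the stretch of genome nearest to each. The number expected was far lower at Chd2, a chromatin remodeller gene, with 5 shared peaks against 0.602, and at Eif4g2, a translation initiation factor gene, with 5 against 0.335. These genes were picked for their many peaks, and the expectation spreads peaks evenly over the genome. Counts above it were therefore not tested as enrichment. Peaks given to these genes lay up to 76.9 kb outside Chd2 and up to 96.7 kb outside Eif4g2.

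In all, 7483 peaks were shared, with at least 1 bp in common. They were 67.0% of the female list (95% exact interval 66.1 to 67.8) and 76.0% of the male list (75.1 to 76.8). Of the 13538 places with a peak in either list, 55.3% were in both. When the female peaks were placed at random on their own chromosomes 1000 times, a mean of 26.9 and at most 45 overlapped a male peak (one-sided permutation p = 0.0010, the smallest that 1000 placements can give). These placements were spread evenly along each chromosome, while the peaks of both lists gathered at gene ends. The placements therefore do not separate binding at the same sites from a common gathering at gene ends. The centres of shared peaks lay a median of 33 bp apart. The remaining 3692 peaks were female-only and 2363 were male-only. Whether a peak missing from 1 list was absent or below the authors' threshold cannot be read from these lists, which carry no signal values.

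At Nr2f2 itself (gene 11819, chromosome 7, 70351946 to 70366746), 1 peak was shared and 2 were female-only. The shared peak lay inside the gene at 70361552 to 70361851. The female-only peaks, at 70280937 to 70281236 and 70337536 to 70337835, lay 70.9 kb and 14.3 kb outside the gene. Nr2f1, the gene of the related receptor COUP-TFI, had 2 shared peaks and 1 female-only peak.

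The 10 genes taken as having the most female-only peaks, with ties broken by symbol, were Msrb3 with 6, Rbms3, Tshz2 and Zbtb7c with 5 each, and Auts2, Fggy, Magi1, Mob3b, Pkdcc and Prkce with 4 each. From the stretch of genome nearest to each gene, 1.74 female-only peaks would be expected at Auts2, 1.72 at Rbms3, 1.1 at Magi1 and between 0.236 and 0.762 at the others. With peaks within 1 kb of each other counted as shared, Zbtb7c had 4 and Auts2 had 3, and the other 8 kept their counts. Msrb3, a methionine sulfoxide reductase gene on chromosome 10 (120781100 to 120899011), had 1 shared and 2 male-only peaks beside its 6 female-only ones. Tshz2, a zinc finger gene, had 7 female peaks and 2 male peaks. Fggy and Mob3b each had 4 female peaks and no male peak. Among genes with the most male-only peaks, Nrp2, a receptor for semaphorins and VEGF, had 3 male peaks and no female peak, at 3.08, 56.0 and 82.8 kb outside the gene on chromosome 1. Kdm7a, a histone demethylase gene, likewise had 3 male peaks and no female peak, and 2 of them lay within 1 kb of a gene end. Meis1, a homeobox gene of mesenchyme, had 5 male peaks, of which 3 were male-only. Dock1, Aff3, Tln2 and Zfp438 also had 3 male-only peaks each. These genes were picked for their counts, and counts this small were not tested gene by gene.

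**Figure D1:**
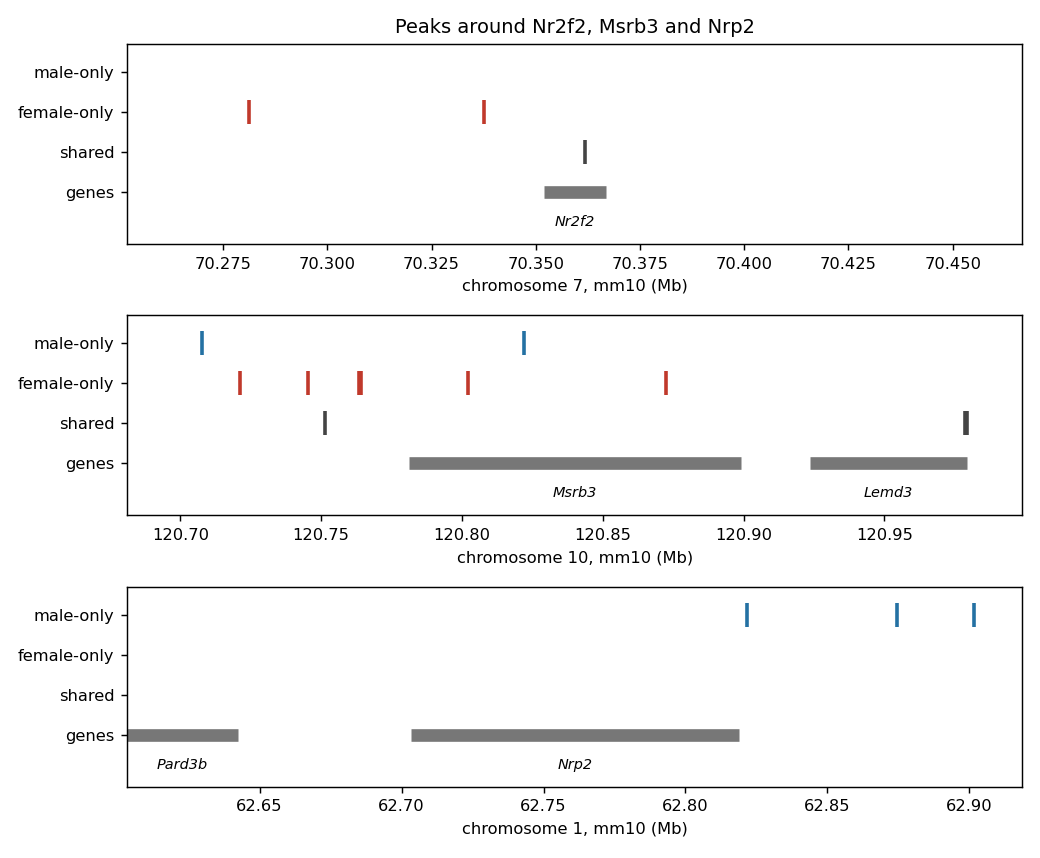
Peak positions around Nr2f2 (chromosome 7), Msrb3 (chromosome 10) and Nrp2 (chromosome 1), drawn to scale in Mb on mm10, with grey bars for protein-coding genes and 1 tick per shared, female-only or male-only peak. Msrb3 has 6 female-only and 2 male-only peaks, and Nrp2 has 3 male-only peaks and no peak of another kind.

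The second comparison concerns the sex chromosomes, where XX and XY chromatin differ in copy number. The X chromosome carried 289 female and 187 male peaks, and 137 of them were shared. There were 152 female-only X peaks against 50 male-only ones. Bcor, Dcx, Emd, Gnl3l, Gpc3, Hs6st2, Mid1ip1, Pdzd4, Prrg3 and Rbbp7 each had 2 female-only peaks, the most for any X gene, and were named after their values were seen. Ties were broken by symbol, so other X genes may also have 2. Bcor also had 1 shared peak, and Mid1ip1 and Prrg3 had 1 male-only peak each. The Y chromosome had 2 peaks, both in the male list. They lay at 808976 to 809275, 9486 bp from Uba1y, and at 1010269 to 1010568, 143 bp from Eif2s3y. The female list had none on the Y chromosome.

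The X chromosome held 2.59% of female peaks (2.30 to 2.90) and 1.90% of male peaks (1.64 to 2.19), an odds ratio of 1.37 against the autosomes (95% interval 1.13 to 1.66, two-sided Fisher's exact p = 0.000816). Between female-only and male-only peaks the odds ratio was 1.98 (1.43 to 2.80, Fisher's exact p = 1.84e-05). Female-only peaks made up 75.2% of the sex-only peaks of the X chromosome (68.7 to 81.0). On the 19 autosomes this share ran from 56.8% to 65.5%, and it was 60.5% for the autosomes pooled. Of the female X peaks, 47.4% were shared, against 67.5% of the female autosomal peaks. For the male list these shares were 73.3% and 76.1%.

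**Figure D2:**
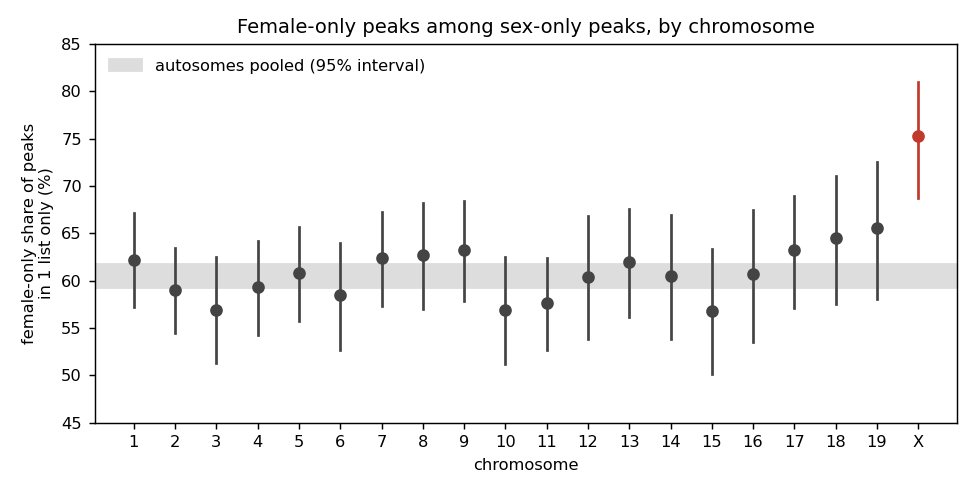
Female-only peaks as a percent of all peaks found in 1 list only, for each autosome and the X chromosome, with 95% exact intervals as vertical lines and the interval of the pooled autosomes as a grey band. The X chromosome lies at 75.2%, above the 19 autosomes, which lie between 56.8% and 65.5%.

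The third comparison asks where peaks lay relative to genes. Peaks gathered at gene ends: Limch1, Osr1, Sfrp2, Ctnnb1 and Etv5 each had a sex-only peak within 1 kb of an end, while the peaks at Igf1 and Hsd17b3 lay between 36.2 and 77.7 kb outside the gene. Of shared peaks, 67.6% lay within 1 kb of the end of an annotated gene (66.5 to 68.6), against 6.05% of genome positions. The share was 60.1% for male-only peaks (58.1 to 62.1) and 40.1% for female-only peaks (38.5 to 41.7). Female-only peaks lay correspondingly more often elsewhere inside genes (34.8%, against 25.9% of male-only peaks) and outside genes (25.1% against 14.0%).

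The odds of lying within 1 kb of a gene end were 0.445 times as high for female-only as for male-only peaks (95% interval 0.399 to 0.495, two-sided Fisher's exact p = 2.62e-52). Female-only peaks were at the lower share on each of the 19 autosomes. Against shared peaks the odds ratio was 0.321 for female-only peaks (Fisher's exact p = 2.05e-168) and 0.722 for male-only peaks (p = 3.53e-11). The X chromosome stood apart: 61.8% of its female-only peaks lay within 1 kb of a gene end (53.6 to 69.6), against 39.2% of autosomal ones (odds ratio 2.52, 1.78 to 3.58, Fisher's exact p = 4.07e-08, a test chosen after these shares were seen). Which end of a gene is its start was not used here, so these shares do not separate promoters from 3′ ends.

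**Figure D3:**
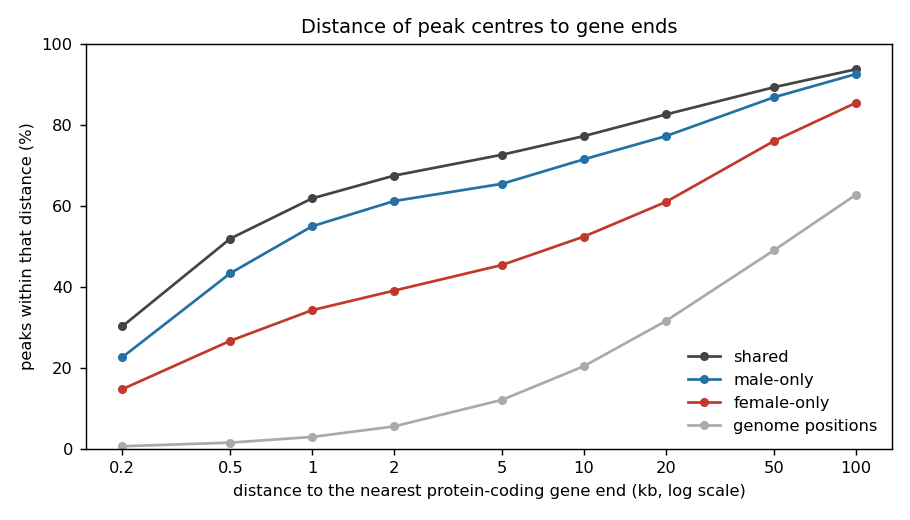
Percent of shared, male-only and female-only peak centres, and of evenly spaced genome positions, within a given distance of the nearest protein-coding gene end (kb, log scale). The female-only line runs below the male-only and shared lines at each distance plotted, and all of them run above the genome positions.

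The fourth comparison asks which groups of genes had COUP-TFII peaks in both sexes. Genes of mesonephric mesenchyme, hedgehog signalling, the cell cycle and the cytosolic ribosome had shared peaks more often than genes with stretches of genome of like length. Those matched genes include families with hardly any peak, such as olfactory receptors (6 of 1106 against 261.7 expected). This lowers the number expected for any list of active genes. Gli1, Gli2 and Gli3 count in both the mesenchymal and the hedgehog list. Of 41 mesenchymal genes, 23 had a shared peak, where 14.1 would be expected from matched random lists (adjusted permutation p = 0.0414, two-sided, with Benjamini-Hochberg adjustment over the 23 lists, as for each list below). Twist2 had 3 shared peaks and Dcn, Foxd2, Gli2, Meis1 and Nr2f1 were among those with 2. Of 17 hedgehog genes, 12 had one against 5.54 expected (adjusted permutation p = 0.023). Among them were Gas1, with 3 shared peaks, Disp1 and Gli2 with 2, and Boc, Cdon, Gli1, Gli3, Smo and Sufu. The call for mesenchymal genes, at 1.63 times expectation, ended when peaks had to lie within 10 kb (1.62 times, adjusted permutation p = 0.106), without the X and Y chromosomes (1.51 times, 0.104) and by the nearest gene end (1.62 times, 0.0515). None of the 41 mesenchymal genes lies on the X or Y chromosome, so leaving these out changed the random lists and not the members. The hedgehog call, at 2.17 times expectation, also ended by the nearest gene end (2.06 times, adjusted permutation p = 0.0515).

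The control lists of widely expressed genes gave the highest ratios. Of 70 genes of cytosolic ribosomal proteins, 39 had a shared peak against 14.7 expected, with 2 shared peaks each at Rpl29, Rplp1, Rps21 and Rps24 (adjusted permutation p = 0.0046). Of 37 cell cycle genes, 23 had one against 9.97, with 2 each at Ccnd3, Ccne1, Cdk6 and E2f3 (adjusted permutation p = 0.0046). Both lists also passed in the whole female list, with 45 and 27 members, and in the whole male list, with 41 and 26 members (adjusted permutation p = 0.0023 for each). Mesenchymal and hedgehog genes passed in neither, at 1.43 and 1.75 times expectation in the female list (adjusted permutation p = 0.0589 for each) and 1.36 and 1.73 times in the male list (adjusted permutation p = 0.214 and 0.0759).

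BMP and TGF-beta genes passed the test in the female list, where 33 of 49 had a peak against 21.6 expected (adjusted permutation p = 0.00920). That call, at 1.53 times expectation, ended when peaks had to lie within 10 kb of the gene (1.36 times, adjusted permutation p = 0.139) or within 1 kb of a gene end (1.36 times, adjusted permutation p = 0.335). In the male list 29 had a peak against 20.2 (adjusted permutation p = 0.0759), and 25 had a shared peak against 16.2 (adjusted permutation p = 0.0607). Smad7, an inhibitor of the pathway, and the BMP receptor gene Bmpr1a each had 3 shared peaks, and Id1 and Id4 had 2. The matrix list had 21 of 40 members with a shared peak against 13.8 (adjusted permutation p = 0.0935), led by Nid2 with 4 and Col1a2 with 3.

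The lists were also tested with shared peaks divided by their distance to gene ends, a split made after the data had been examined. With shared peaks over 1 kb from every protein-coding gene end, mesenchymal genes (17 with a peak against 6.50 expected, adjusted permutation p = 0.0069), BMP and TGF-beta genes (17 against 7.25, adjusted permutation p = 0.0069) and matrix genes (14 against 6.57, adjusted permutation p = 0.0322) had peaks more often than matched lists. With shared peaks within 1 kb of an end, ribosomal protein genes (35 against 12.4, adjusted permutation p = 0.0046) and cell cycle genes (17 against 7.47, adjusted permutation p = 0.0138) did so, while 8 mesenchymal genes had one against 9.10. Ribosomal protein genes also passed with the distant peaks (8 against 2.66, adjusted permutation p = 0.0403). Cell cycle genes did not (7 against 3.10, adjusted permutation p = 0.185), although their ratio to expectation was 2.26 there and 2.28 near gene ends. Hedgehog genes passed with neither the near peaks (8 against 3.56, a ratio of 2.25, adjusted permutation p = 0.190) nor the distant ones (5 against 2.52, a ratio of 1.99, adjusted permutation p = 0.35). With distant peaks of the whole female list, ribosomal protein genes (2.38 times expectation, adjusted permutation p = 0.0644) and cell cycle genes (1.81 times, adjusted permutation p = 0.258) did not pass. Matrix genes did not pass there either (1.49 times, adjusted permutation p = 0.258). Mesenchymal genes (2.17 times) and BMP and TGF-beta genes (1.94 times) did (adjusted permutation p = 0.0023 for each). Near and distant peaks were not tested against each other.

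Lists of the ducts and of steroid action lay within the 95% range of matched lists. This held for 6 of 25 Wolffian duct genes (8.23 expected, adjusted permutation p = 0.782), with 2 shared peaks at Fgfr2, Pax8 and Spry1, and for 8 of 25 Müllerian duct genes (7.76 expected). It also held for 10 of 25 genes of androgen and estrogen action (8.90 expected), among them Igf1 and Sfrp1 with 3 shared peaks each, Ncoa2 with 2 and the estrogen receptor gene Esr1 with 1. Shared peaks were found at 11 of 34 FGF genes (10.9 expected), 18 of 56 WNT genes (18.3), 8 of 39 Hox genes (8.10), 15 of 48 nuclear receptor genes (15.4) and 9 of 25 genes named as COUP-TFII targets in other tissues (8.80). Maml3, with 5, and Dll4, with 3, led the 10 of 23 Notch genes (6.94 expected). The counts were 8 of 18 for smooth muscle (5.46), 4 of 20 for the retinoic acid pathway (6.01), 5 of 20 for endothelium (6.33) and 3 of 15 for germ cells (4.25).

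Lists of other tissues and cell types were at the low end, and of these gonadal, neuronal, liver and blood lists none passed the test. Shared peaks were found at 3 of 26 gonadal somatic genes (Bmp2, Gata4 and Sox8, with 7.86 expected), 2 of 20 neuronal genes (Erbb3 and Snap25, 6.20), 2 of 24 liver plasma protein genes (Apob and Fgg, 6.38) and 1 of 20 blood and immune genes (Klf1, 4.98). The adjusted permutation p was 0.123 for each of these 4 lists.

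**Figure D4:**
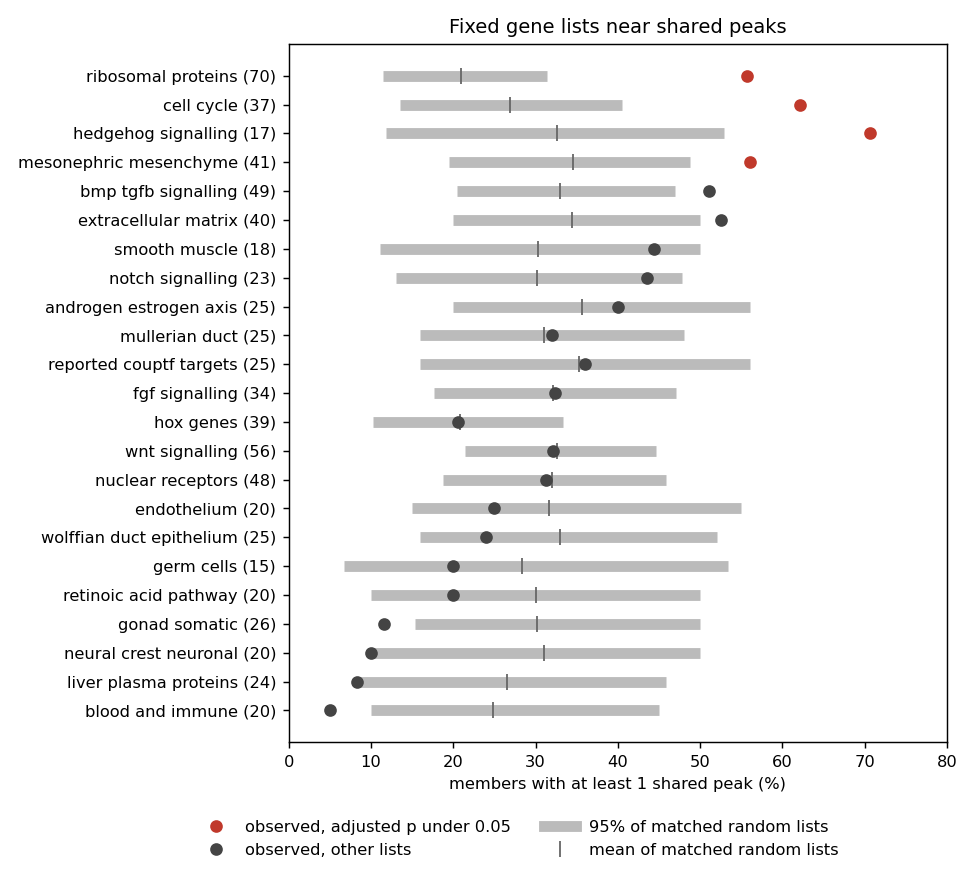
Percent of the members of each of the 23 fixed gene lists with at least 1 shared peak (points; members in parentheses), with the mean (tick) and 95% range (grey bar) of 10000 random lists matched on territory. Red points mark the 4 lists with an adjusted p under 0.05, which are ribosomal proteins, cell cycle, hedgehog signalling and mesonephric mesenchyme.

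The last comparison asks whether any of these groups had peaks more often in 1 sex. Some duct and hormone genes had a peak called in 1 list only. Over all genes and places, 33.0% of female peaks and 24.0% of male peaks were in 1 list only. The genes below are therefore examples, and their differences were not tested singly. Srd5a2, whose enzyme converts testosterone to dihydrotestosterone, and Ncoa1, a coactivator gene, each had 2 female-only peaks and no male peak. Egf, Hsd17b3, which encodes an enzyme of testosterone synthesis, and Sfrp2 each had 1 male peak and no female peak.

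Among Wolffian duct genes, Gdnf, the ligand of the Ret receptor, had 1 female-only peak, 9.01 kb outside the gene. Ctnnb1, Etv5, Hoxb7 and Krt8 each had 1 male-only peak. Among Müllerian duct genes, Limch1, Osr1 and Smad1 had 1 female-only peak each, and Foxj1, Hoxa13 and Hoxa9 had 1 male-only peak each. Emx2, needed for both ducts, had 3 female-only peaks beside its shared one, and Esr1 had 2 beside its shared one.

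None of the 23 lists differed between female-only and male-only peaks (two-sided Fisher's exact test with Benjamini-Hochberg adjustment, smallest adjusted p = 0.935), and 0 had an unadjusted p under 0.05. The smallest unadjusted exact p, 0.0627, was that of the mesenchymal genes, with 23 female-only and 7 male-only peaks (odds ratio 2.23, 0.926 to 6.17). The androgen and estrogen list had 8 and 4 (1.36, 0.363 to 6.16), as did the Müllerian list, and the Wolffian list had 11 and 7 (1.06, 0.376 to 3.24). Against matched random lists, 0 lists passed with female-only peaks and 0 with male-only peaks. The nearest by unadjusted p were hedgehog genes with female-only peaks (8 of 17 against 3.29, adjusted permutation p = 0.112) and FGF genes with male-only peaks (11 of 34 against 4.12, adjusted permutation p = 0.0644). With female-only peaks, mesenchymal, WNT, and BMP and TGF-beta genes had the same adjusted permutation p of 0.112. So did the control list of ribosomal proteins (11 of 70 against 5.13). The intervals of the odds ratios between female-only and male-only peaks leave a difference of more than 3-fold open in at least 1 direction for each list.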

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

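The test on the X copies was chosen after its result had been seen. Those on single X genes, on the X excess and on male promoters were set before.

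Female-only and male-only peaks differed in how often they lay on the X chromosome, with an odds ratio of 1.985 against the autosomes (1.43 to 2.80). Binding of a few X genes in female cells alone would concentrate these peaks, yet the 10 genes with most of them held 13.16%, inside the 10.5 to 15.1% of random draws of female X peaks. An extra X copy in XX chromatin was assumed, without a test, to raise the share along the whole chromosome. The lowest of 4 equal stretches of the X, at 68.97% female-only, had an interval (49.2 to 84.7) that holds the 60.5% of the pooled autosomes. The other stretches, at 78.0%, 78.7% and 73.1%, had intervals above it, with lower ends of 65.3%, 64.3% and 60.9%. With the lowest stretch unresolved, the explanation by X copies stays open. A sex difference in COUP-TFII binding to the X chromosome stays open and untested, since sex and copy number cannot be separated in this design.

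Female-only and male-only peaks also differed in their distance to genes, with an odds ratio of 0.4446 for a gene end within 1 kb (0.399 to 0.495). The X excess is not the source, because the ratio was 0.4274 (0.383 to 0.476) without the X and Y chromosomes. Background capture of open promoters in the male chromatin could bring male-only peaks to genes active in all cells, and the odds ratio of mitochondrial ribosome and proteasome genes among sex-only peaks near gene ends, male against female, was 0.9737, but with 8 such peaks in each list its interval (0.318 to 2.99) leaves this open. A different enrichment or threshold between the lists, and a sex difference in binding far from gene ends, stay open and untested.

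On sequences not placed on a chromosome, there were 7 peaks in the female list and 6 in the male list, more than the fixed limit of 3 used for flagging. Of the 7 female peaks, 6 were shared. The overlap counts these peaks, but the chromosome, location and gene list values leave them out.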

How the results depend on the processing

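The number of shared peaks (6428 to 8031 against 7483), the odds ratios of the X chromosome and of gene ends, and the 0 lists that differed between female-only and male-only peaks kept their direction and side of the threshold under each alternative run. What depended on the processing was how many of the 23 gene lists passed against random lists, and the cause was not tested. For the female list, 3 passed as reported, 10 by the exact binomial test on territories, 6 with random lists not matched on territory, 6 by the nearest gene end and 6 with membership rotated along the gene order. For the male list, 2 passed as reported, and 8, 7, 5 and 7 in the same settings, with 6 for peaks over 1 kb from gene ends. For shared peaks, 4 passed as reported, 9 by the binomial test, 2 by the nearest gene end and 2 for peaks within 1 kb of a gene end. For female-only peaks, 0 passed as reported, 1 with genes within 500 kb, 7 by the binomial test, 5 with unmatched lists, 5 with rotated membership and 3 for peaks over 1 kb from gene ends. For male-only peaks, 0 passed as reported, 2 by the binomial test, 1 with unmatched lists and 1 with rotated membership. Peaks within 1 kb of a gene end turned the ratio of mesenchymal genes with a shared peak from 1.63 to 0.8795. The binomial test uses another measure: all peaks of a list's genes, and not members with a peak, against their share of the genome. By it, Hox genes, below expectation as reported, stood at 3.158 times it in the female list and 3.86 with shared peaks. In the female list these were 11 peaks against 3.48, beside 8 members against 10.5 as reported. Germ cell genes stood at 2.345 and 2.547, and 7 of their 11 female peaks lay at Tex14. All of these ratios were past the threshold. Of 621 values for single lists, 409 kept direction without passing in either setting, 69 kept direction and passed in both, 75 turned direction without passing in either setting, 52 passed only in the alternative with direction kept and 11 no longer passed with direction kept. The shares of peaks near a gene end moved in 6 cases, with the distance set at 2.5 kb or with other genes than protein-coding left out. The nearest gene end, rotated membership, the split at 1 kb, leaving out the X and Y chromosomes and the wider definition of a shared peak for single genes, the X chromosome and gene ends were chosen after seeing the data.

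No paired analysis was possible because each sex has 1 list over both replicates, and for the same reason no replicate was left out. Alternatives that need a peak score, and all motif alternatives, were not run. The depth of the libraries is unknown. Of lists raised 2-fold in simulations of evenly spread peaks, as many as the shared ones, 11 of 50 were called. That rate need not hold for the real peaks. The smaller female-only and male-only sets and the comparison between them were not simulated.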

Other observations

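Families of genes defined by symbol, chosen after the data had been examined, were tested for peaks in the same way, with adjustment over 21 families. Of 78 mitochondrial ribosome genes, 42 had a shared peak against 17.9 expected, among them Mrps9, Mrpl41 and Mrps2 (adjusted permutation p = 0.0007). Of 397 Zfp zinc finger genes, 174 had one against 111.4 (adjusted permutation p = 0.0007). Other families had few: 6 of 1106 olfactory receptor genes against 261.7, 3 of 353 vomeronasal receptor genes against 101.9, 7 of 95 cytochrome P450 genes against 28.2 and 11 of 120 genes with interleukin or chemokine symbols against 33.4 (adjusted permutation p = 0.0007 for each), and 2 of 53 keratin genes against 12.4 (0.0018). The interleukin and chemokine symbols take in receptor genes such as Il4ra and Il6st, both with a shared peak. Collagens (15 of 44 against 15.1) and forkhead factors (12 of 44 against 13.6) lay within the range of matched lists.

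Among female-only peaks, 3 families had more members with a peak than matched lists, and olfactory receptors, vomeronasal receptors and cytochromes P450 had fewer. Of 29 semaphorin and plexin genes, 12 had a female-only peak against 5.25 expected (adjusted permutation p = 0.0185), among them Sema3a, Sema3c, Sema3d, Sema6d, Plxna1 and Plxnb2. Of 22 ephrin and Eph receptor genes, 10 had one against 4.07 (adjusted permutation p = 0.0185), among them Efnb2, Efna5, Epha7 and Ephb3. Of 78 mitochondrial ribosome genes, 14 had one against 6.83 (adjusted permutation p = 0.0462). With male-only peaks 5 members of each of these families were found, against 3.53, 2.75 and 5.26 expected. The direct comparison of female-only with male-only peaks did not separate the lists, with 15 against 5 peaks for semaphorins and plexins (odds ratio 2.04, 0.702 to 7.17, adjusted Fisher's exact p = 0.914), 11 against 5 for ephrins (1.49, 0.477 to 5.48, 0.914) and 14 against 5 for the mitochondrial ribosome (1.90, 0.645 to 6.75, 0.914).

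The high share of ribosomal protein and cell cycle genes with a shared peak was weighed against technical explanations. Reads shared with ribosomal protein pseudogenes stay open: 0 of 318 such copies had a shared peak within 1 kb, against 81 of 10111 other pseudogenes (odds ratio 0, interval up to 1.48), but the interval holds 1, and reads placed on the parent gene or dropped would leave none at the copies. Open promoters of widely expressed genes in general could give the pattern: mitochondrial ribosome and proteasome genes together stood at 1.987 times expectation (59 of 126 against a range of 21 to 39), while olfactory receptor genes fell below theirs, although proteasome genes alone did not pass with shared peaks (17 of 48 against 11.8, adjusted permutation p = 0.198) or in the female list (21 against 15.3, 0.161), and did in the male list (25 against 14.7, adjusted permutation p = 0.00607). Whether COUP-TFII itself binds there stays open, because input and signal values were not analysed here.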
